A study of Mus musculus with 21 samples.

How the data were processed

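The study measured messenger RNA in bone-marrow-derived macrophages by sequencing total RNA extracted with Trizol. The values used here are the deposited counts of reads per gene, whole numbers in 1 table of 47069 gene identifiers and 21 libraries, with no normalization by the authors. Per the submitters' processing notes, TopHat2 2.0.12, featureCounts of Subread 1.6.3, edgeR 3.28.1 and the mouse genome GRCm38 were used. The annotation, the strand setting and the way pairs of reads were counted are not given in the sources used here. Counts of 2 (30373 values) outnumbered counts of 1 (17808), and counts of 4 (14538) outnumbered counts of 3 (9055), so many fragments appear to be counted once per mate and counting intervals are then too narrow. Since the strand is not given, reads of overlapping antisense genes can be counted for either gene.

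From these counts everything below was computed with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Identifiers were matched to symbols and to positions in GRCm38.p6 with gene tables, which gave a symbol to 32832 of them, and 2596 older symbols were replaced by the current one. Of 32292 identifiers with a count, 15581 passed the filter filterByExpr of edgeR by group, 14023 of them with a symbol. Libraries were scaled by the trimmed mean of M values (TMM). A negative binomial model with 1 term per group was fitted to all 21 libraries, and each contrast was tested with the quasi-likelihood F test of edgeR. Adjusted p values are those of Benjamini and Hochberg over all genes tested, with a threshold of 0.05. The common biological coefficient of variation was 22.8%. There were 16 contrasts, of which 13 compared a pair of groups. The interaction at each time was the effect of TNF with IL minus its effect without IL, the latter against Ctrl_0h at 0 h, and the change with time was the effect of TNF with IL at 24 h minus that at 6 h.

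Levels are CPM with library totals scaled by TMM. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, a ratio is given with a 95% interval of the counting error. Intervals and floors cover counting error only, and reads are not independent molecules.

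The groups, contrasts, gene lists, thresholds and alternatives, and the rule for named genes, were set before the data were examined. The rule names for each contrast the 10 raised and 10 lowered genes with the largest log2 fold change, among genes called, with at least 10 CPM in the higher group and no overlap between the libraries of the groups compared, which chance gives in 10% of cases for 3 against 3. It leaves out predicted genes and pseudogenes. It adds 15 marker genes, which are Arg1, Retnla, Chil3, Mrc1, Ccl17, Ccl24, Tnf, Nos2, Il1b, Tnfaip3, Nfkbia, Socs1, Socs3, Il4ra and Tnfrsf1b. Members of gene lists were chosen as examples after their values were seen, as were Xist, Ddx3y and Ifi202b as examples for single libraries. Results of some genes that the rule or a gene list names are not reported here.

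Written from general knowledge, 14 function lists and 7 lists of markers of other cell types held 367 genes, of which 3 had no match. The function lists were alternative activation, NF-kB and inflammatory genes, interferon-stimulated genes, MHC class II presentation, cell cycle, cholesterol synthesis and uptake, cholesterol efflux and LXR targets, glycolysis, respiratory chain, lysosome, signalling feedback, cytokine receptors and JAK-STAT6 components, macrophage identity, and osteoclast and cell fusion genes. The cell type lists were neutrophil, eosinophil with mast cell and basophil, fibroblast and stromal, T and NK cell, B cell, dendritic cell, and erythroid. Each function list was tested in each contrast with camera of limma on log CPM with a prior count of 2, at a preset correlation of 0.01 between genes, and p values were adjusted over all lists and contrasts. The same test with a correlation estimated from the data is given where it ended a call. Calls of members were also adjusted over the list alone.

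The share of IL-raised genes lowered by TNF took genes called and raised at least 2-fold by IL against Ctrl_0h, with a Wilson interval. The alternatives were DESeq2 size factors, the DESeq2 Wald test, no filter, a strict filter of 1 CPM in 3 libraries, a fit of the compared groups alone, the replicate number as a block, each library left out in turn, and 3 libraries left out together. Simulated counts of all 21 libraries were drawn from the group means and the fitted spread of each gene. IL_TNF_6h was given the means of IL_6h, with changes added to known genes. These draws held no library that stands apart from its group. The method was tested on them over 15323 genes. It recovered 54 of 100 changes of 2-fold and 77 of 100 of 4-fold, with median estimates of 0.97 and 2.06 on the log2 scale, and 2 of 133 calls were false. In a separate simulation over 15303 genes the lysosome list was raised by 0.5 on the log2 scale, and it was called (adjusted p 5.76e-33) and 0 other lists were. No replicate of a group was a duplicate of another, the lowest chi-square per degree of freedom between replicates being 7.50, and libraries of different groups were not compared in this way. Reads of mitochondrial genes made up between 0.599% and 2.21% of each library.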

Results

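RNA was sequenced from bone-marrow-derived macrophages, which are macrophages grown in culture from the bone marrow of wild-type C57BL/6 mice with the growth factor M-CSF. The cells were left untreated, or received interleukin 4 (IL-4) and interleukin 13 (IL-13), tumour necrosis factor (TNF), or all 3 cytokines, each at 10 ng/ml. Each treatment was sampled after 6 h and after 24 h, and the untreated cells at 0 h, so every comparison with untreated cells also carries the time in culture. This gave 7 groups of 3 libraries, 21 in all, called Ctrl_0h, IL_6h, TNF_6h, IL_TNF_6h, IL_24h, TNF_24h and IL_TNF_24h here, where IL stands for IL-4 with IL-13. The libraries held between 28.1 and 48.7 M counts (M, 1e6) in genes. Of 47069 gene identifiers, 15581 passed the filter on low counts and were tested, and they held 99.9% of the counts. Levels are given as CPM, which are counts scaled to a common library total, mean ± SD with n = 3, and changes as log2 fold changes ± standard error. Genes were tested with the quasi-likelihood F test of edgeR, and a gene was called at an adjusted p below 0.05. The standard error was worked back from this test, as the size of the log2 fold change over the square root of F. For genes with few counts in a group it is too narrow and does not cover the dependence on single libraries. The value of Chil3 in IL_6h against Ctrl_0h, for example, moved from 7.68 to 12.38 without replicate 2 of Ctrl_0h. The labels do not state whether the 3 libraries of a group came from separate cultures or animals, so the p values measure only the spread between these samples.

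The libraries fell into 3 sets by sex-linked genes and by the last rows of the table, and the gene Ifi202b followed 1 of the sets. Xist, the RNA of the inactive X chromosome in female cells (ENSMUSG00000086503, chromosome X, 103460373 to 103483233 in GRCm38.p6), had at least 162 CPM in the 15 libraries outside IL_24h and IL_TNF_24h and at most 0.145 CPM in those 6. Ddx3y, a helicase gene on the Y chromosome (ENSMUSG00000069045, chromosome Y, 1260715 to 1286628), had between 41.8 and 50.9 CPM in these 6 libraries and 0 counts in the 15 others. Ifi202b, an interferon-inducible gene (ENSMUSG00000026535, chromosome 1, 173962569 to 173982844), had between 30.3 and 64.2 CPM in the 6 libraries of IL_6h and IL_TNF_6h and 0 counts in the 15 others. The last 86 gene identifiers of the table were taken as those after the last one with a count in Ctrl_0h, TNF_6h or TNF_24h. They thus had 0 counts in these 9 libraries. Of them, 39 had counts in the 12 libraries with IL, where they summed to between 10263 and 19757 per library. Comparisons of TNF with Ctrl_0h, of TNF between times, and of IL_TNF with IL at 1 time lay inside a set. All others compared libraries of different sets, so any difference between sets adds to the effect of the cytokines in them.

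Replicate 2 of Ctrl_0h had counts in 27761 genes, against between 16996 and 20631 in the 20 other libraries. Of 3381 protein-coding genes without a count in the 20 others, 1384 had counts in it. Of 162 named genes, raised or lowered, 47 were at least 3 times as high in it as in the other Ctrl_0h libraries. Reg2 had 509.5 CPM there and 1.34 and 2.81 CPM in replicates 1 and 3. In IL_TNF_24h, replicate 1 had 269 CPM of Nos2 against 46.2 and 44.6 in replicates 2 and 3, and 72.9 CPM of Retnla against 315 and 273. By the chi-square per degree of freedom between replicates, replicate 2 of IL_6h (154 and 87.1) and replicate 3 of IL_TNF_6h (108 and 88.7) differed from their groups as much as replicate 2 of Ctrl_0h (89.2 and 84.5) and replicate 1 of IL_TNF_24h (96.6 and 98.7), as did replicates 1 and 3 of TNF_24h from each other (107). The first 2 had more Col1a1, a collagen gene, with 5.234 and 4.076 CPM against at most 0.171 CPM in the other libraries of these groups. An alternative chosen after the data were seen left out replicate 2 of Ctrl_0h, replicate 1 of IL_TNF_24h and replicate 3 of TNF_6h, which had 20631 genes with a count but lay close to its replicates (14.4 and 17.0), and is called the 3 libraries left out here.

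**Figure D1:**
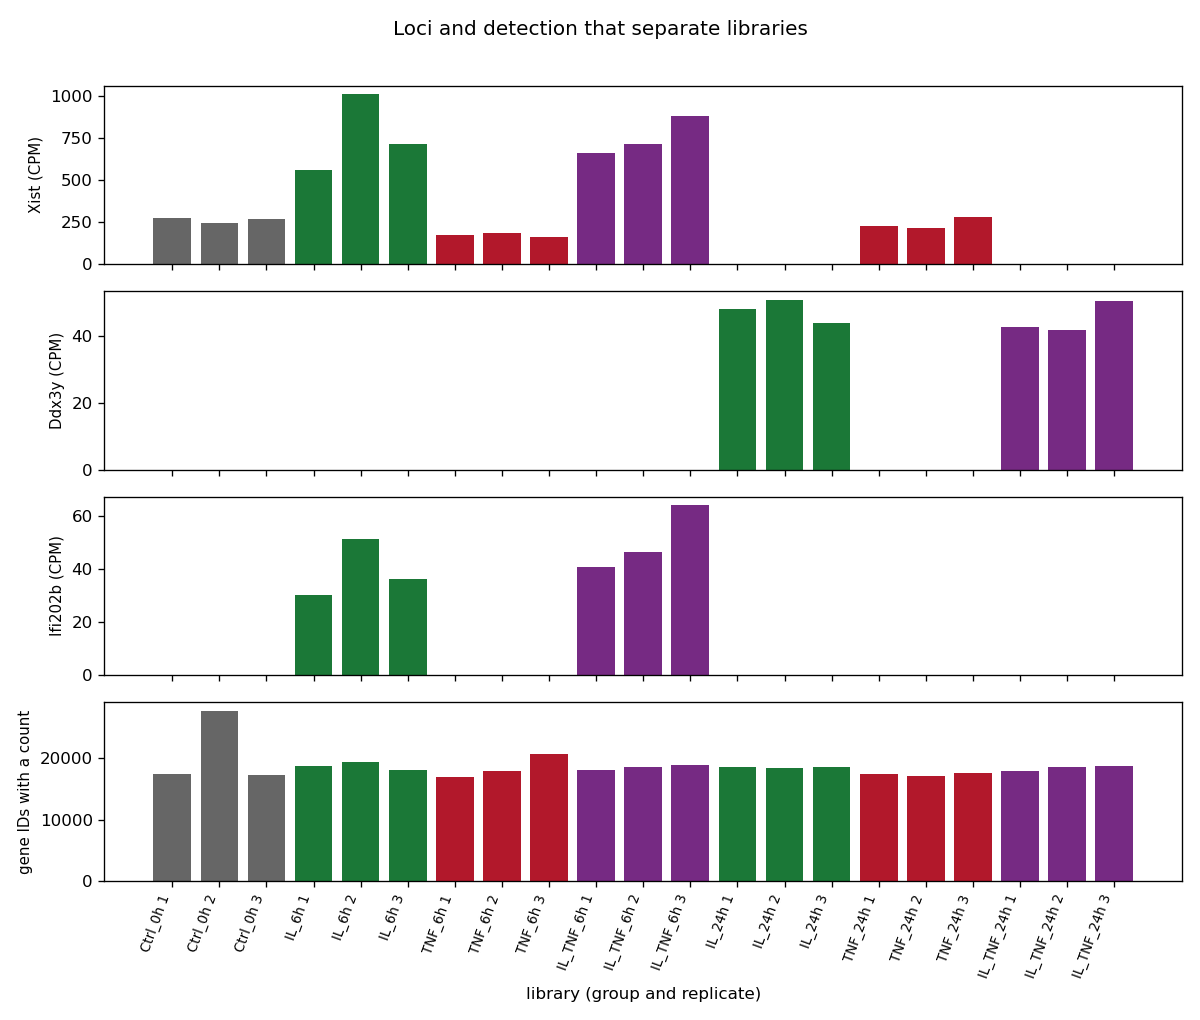
Bars show, for each of the 21 libraries, the CPM of Xist, Ddx3y and Ifi202b and the number of gene identifiers with a count. Ddx3y was present only in the 6 libraries of IL_24h and IL_TNF_24h, Ifi202b only in the 6 of IL_6h and IL_TNF_6h, and replicate 2 of Ctrl_0h had 27761 identifiers with a count.

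IL_6h was compared with Ctrl_0h to find the early response to IL-4 and IL-13, the cytokines of alternative macrophage activation. Arg1, which encodes arginase (ENSMUSG00000019987, chromosome 10, 24915207 to 24927470), rose from 0.0356 ± 0.0617 to 248 ± 20.1 CPM. Retnla, a secreted resistin-like protein (ENSMUSG00000061100, chromosome 16, 48842609 to 48844461), had 0 counts in Ctrl_0h and 36.7 ± 7.31 CPM in IL_6h, a rise of at least 1214-fold. Chil3, a chitinase-like secreted protein (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), rose from 0.0902 ± 0.156 to 17.5 ± 1.66 CPM, and Mrc1, the mannose receptor (ENSMUSG00000026712, chromosome 2, 14229414 to 14332023), from 161 ± 31.5 to 1043 ± 128 CPM. Slc7a2, a transporter that brings arginine into the cell, rose from 2.502 ± 0.703 to 632 ± 153 CPM. The log2 fold changes were 12.46 ± 0.44 for Arg1, 7.68 ± 0.47 for Chil3, 7.97 ± 0.30 for Slc7a2 and 2.70 ± 0.16 for Mrc1. All counts of Arg1 in Ctrl_0h lay in replicate 1 and all of Chil3 in replicate 2, so without that library these genes rose from 0 counts and the size of the rise is open. Among the largest rises were also those of the transmembrane protein gene Tmem26 (log2 fold change 8.42 ± 0.33), the sodium channel gene Scn3a (8.41 ± 0.53), the adhesion molecule gene Pecam1 (8.22 ± 0.51), the Ras exchange factor gene Rasgrp1 (7.31 ± 0.40) and Apol7c of the apolipoprotein L family (7.15 ± 0.52). When replicate 2 of Ctrl_0h was left out, Scn3a rose from 0 counts, Pecam1 by 10.06 and Apol7c by 8.53.

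Genes of dividing cells were among those that fell most in IL_6h. The kinetochore genes Cenpm (log2 fold change -7.63 ± 0.69), Ska1 (-6.63 ± 0.63) and Spc24 (-6.59 ± 0.58) fell, as did Sapcd2, Aunip and Pimreg, which act in mitosis (-7.12, -7.03 and -6.68). Ighm, the heavy chain of immunoglobulin M, went from 84.2 ± 11.4 to 0.264 ± 0.130 CPM. Mtcl1, Sdk1 and Prob1 also had large falls (log2 fold changes -9.47, -8.24 and -7.40), and all 3 rested in large part on replicate 2 of Ctrl_0h, where Mtcl1 had 159 CPM against 0.294 and 1.17 in the other replicates.

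Tnfaip3, an inhibitor of NF-kB signalling, rose at 6 h of IL from 7.60 ± 2.01 to 69.9 ± 3.92 CPM, Tnfrsf1b, a TNF receptor, from 222 ± 36.2 to 1068 ± 54.7 CPM, and Socs1, an inhibitor of cytokine receptor signalling, from 9.29 ± 6.94 to 43.2 ± 10.5 CPM. Nfkbia, another NF-kB inhibitor, rose by 0.74 on the log2 scale and the cytokine gene Il1b by 3.03 (4.09 without replicate 1 of Ctrl_0h). The chemokine gene Ccl24 rose by 1.79, and the level of the chemokine gene Ccl17 was 44.9 (95% interval of the counting error 12.2 to 376) times that of Ctrl_0h. Tnf (adjusted p 0.869), Nos2 (0.175), Socs3 (0.739) and the IL-4 receptor gene Il4ra (0.0782) were not called. Without replicate 2 of Ctrl_0h, Socs3 was called as raised (log2 fold change 0.95), Nos2 as raised from 0 counts and Il4ra as lowered (-0.44).

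10043 genes were called between IL_6h and Ctrl_0h, 5117 raised and 4926 lowered. Gene lists were tested with camera at a preset correlation between genes, and the number of members called when adjusted over the list alone is given where it differed in the direction named. Of 29 genes of alternative activation, 26 rose and 2 fell (26 and 2 when adjusted over the list alone; camera adjusted p 2.09e-09). Of 33 NF-kB and inflammatory genes, 25 rose and 1 fell (26 and 1 over the list alone; adjusted p 1.46e-06), with Ptgs2, which encodes cyclooxygenase 2, at 4.74 ± 0.73. All 30 cell cycle genes fell, also over the list alone (adjusted p 4.49e-14), with a log2 fold change of -6.56 ± 0.62 for Ube2c and -6.15 ± 0.44 for Birc5, but the list was not called with an estimated correlation (adjusted p = 0.247 with an estimated correlation). Of 37 genes of the respiratory chain, 32 fell and 3 rose, with the same counts over the list alone (adjusted p = 5.48e-07, adjusted p = 0.381 with an estimated correlation). Ndufa2 of complex I changed by -2.33 ± 0.23. Of 17 cytokine receptor and JAK-STAT6 genes, 10 rose, among them the kinase gene Jak2 at 3.02 ± 0.17 (adjusted p = 0.0241, adjusted p = 0.556 with an estimated correlation, adjusted p = 0.0936 with the 3 libraries left out). The signalling feedback list (9 of 15 raised, 10 over the list alone) had an adjusted p = 0.0106, and adjusted p = 0.218 with an estimated correlation. Glycolysis was not called as a list (adjusted p 0.0671), with 11 of 16 genes lowered and Hk2 raised by 2.51. The lysosome (0.232), cholesterol synthesis (0.601), cholesterol efflux (0.820), macrophage identity (0.312) and osteoclast and fusion lists (0.0656) were not called. The comparison also carries the time in culture and the difference between sets, since there was no untreated group at 6 h.

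IL_24h was compared with Ctrl_0h to find the later response to IL-4 and IL-13. Retnla reached 2507 ± 161 CPM against 0 counts in Ctrl_0h, at least 81271-fold, and Chil3 reached 245 ± 6.14 CPM (log2 fold change 11.48 ± 0.47). Arg1 stood at 55.2 ± 6.50 CPM (10.29 ± 0.44) and Mrc1 at 573 ± 45.5 CPM (1.83 ± 0.15). The eosinophil-associated ribonuclease genes Ear2 and Rnase2a rose to 78.7 ± 1.49 and 191 ± 7.06 CPM, and reads of such closely related genes can be assigned to the wrong copy. Fibronectin (Fn1) rose from 0.490 ± 0.311 to 247 ± 20.5 CPM. The level of Il31ra, a receptor chain for interleukin 31, was 1332 (95% interval of the counting error 239 to 52623) times that of Ctrl_0h. Ccl17 was at 311 (85.8 to 2571) times its level in Ctrl_0h and Ccl24 rose by 3.49 ± 0.36. Without replicate 1 of Ctrl_0h Arg1 rose from 0 counts, as did Chil3, Ear2, Rnase2a and Il31ra without replicate 2. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were also among the 10 largest rises and Xist among the 10 largest falls (log2 fold change -11.71), as they mark the set of these libraries.

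Hpgd, which degrades prostaglandins, fell from 131 ± 12.6 to 3.69 ± 0.276 CPM in IL_24h. Cx3cr1, the fractalkine receptor, fell from 67.5 ± 5.72 to 1.21 ± 0.266 CPM and the kinase gene Dmpk from 51.0 ± 9.80 to 0.963 ± 0.193 CPM. The falls of Onecut3, Mtcl1, Mycl, Sdk1, Sema6c and Galnt3 rested in large part on replicate 2 of Ctrl_0h, where Onecut3 had 80.2 CPM against 0.107 and 0.326. Tnf fell to 7.92 ± 0.124 from 26.3 ± 3.90 CPM (log2 fold change -1.73 ± 0.15), and Socs3 (-1.53 ± 0.34) and Nfkbia (-0.46 ± 0.12) fell as well. The size of the fall of Socs3 rested in part on replicate 2 of Ctrl_0h, with 16.5 CPM against 4.70 and 5.25 in replicates 1 and 3. Tnfaip3 rose by 1.76, Socs1 by 2.04 and Tnfrsf1b by 2.11. Nos2 (adjusted p 0.630), Il1b (0.480) and Il4ra (0.126) were not called. Without replicate 2 of Ctrl_0h, Nos2 was called as raised from 0 counts and Il4ra as lowered (log2 fold change -0.40).

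10020 genes were called between IL_24h and Ctrl_0h, 4938 raised and 5082 lowered. Of 29 alternative activation genes 25 rose and 1 fell (25 and 2 over the list alone; adjusted p 8.56e-12). Of 7 osteoclast and fusion genes 6 rose (adjusted p 3.40e-04), with the fusion protein genes Ocstamp at 7.68 ± 0.40 and Dcstamp at 4.67 ± 0.18. Of 18 genes of cholesterol synthesis and uptake, 14 rose, with adjusted p = 0.00163 and adjusted p = 0.328 with an estimated correlation. In the list of MHC class II presentation 7 of 11 genes rose, H2-Aa by 3.02 ± 0.16 (adjusted p = 0.00924, adjusted p = 0.306 with an estimated correlation). Of 30 cell cycle genes 21 fell and 0 rose (adjusted p = 1.94e-04, adjusted p = 0.584 with an estimated correlation). 15 of 33 interferon-stimulated genes fell and 5 rose (adjusted p = 0.0253, adjusted p = 0.755 with an estimated correlation). With the 3 libraries left out camera called this list as lowered here (adjusted p 1.21e-06) and as raised in IL_6h against Ctrl_0h (0.0218). The NF-kB list had 10 genes raised and 10 lowered and was not called (adjusted p 0.924). Apoe, the main apolipoprotein of macrophages, fell from 11256 ± 707 to 1137 ± 86.1 CPM, while its list of cholesterol efflux was not called (adjusted p 0.266).

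**Figure D2:**
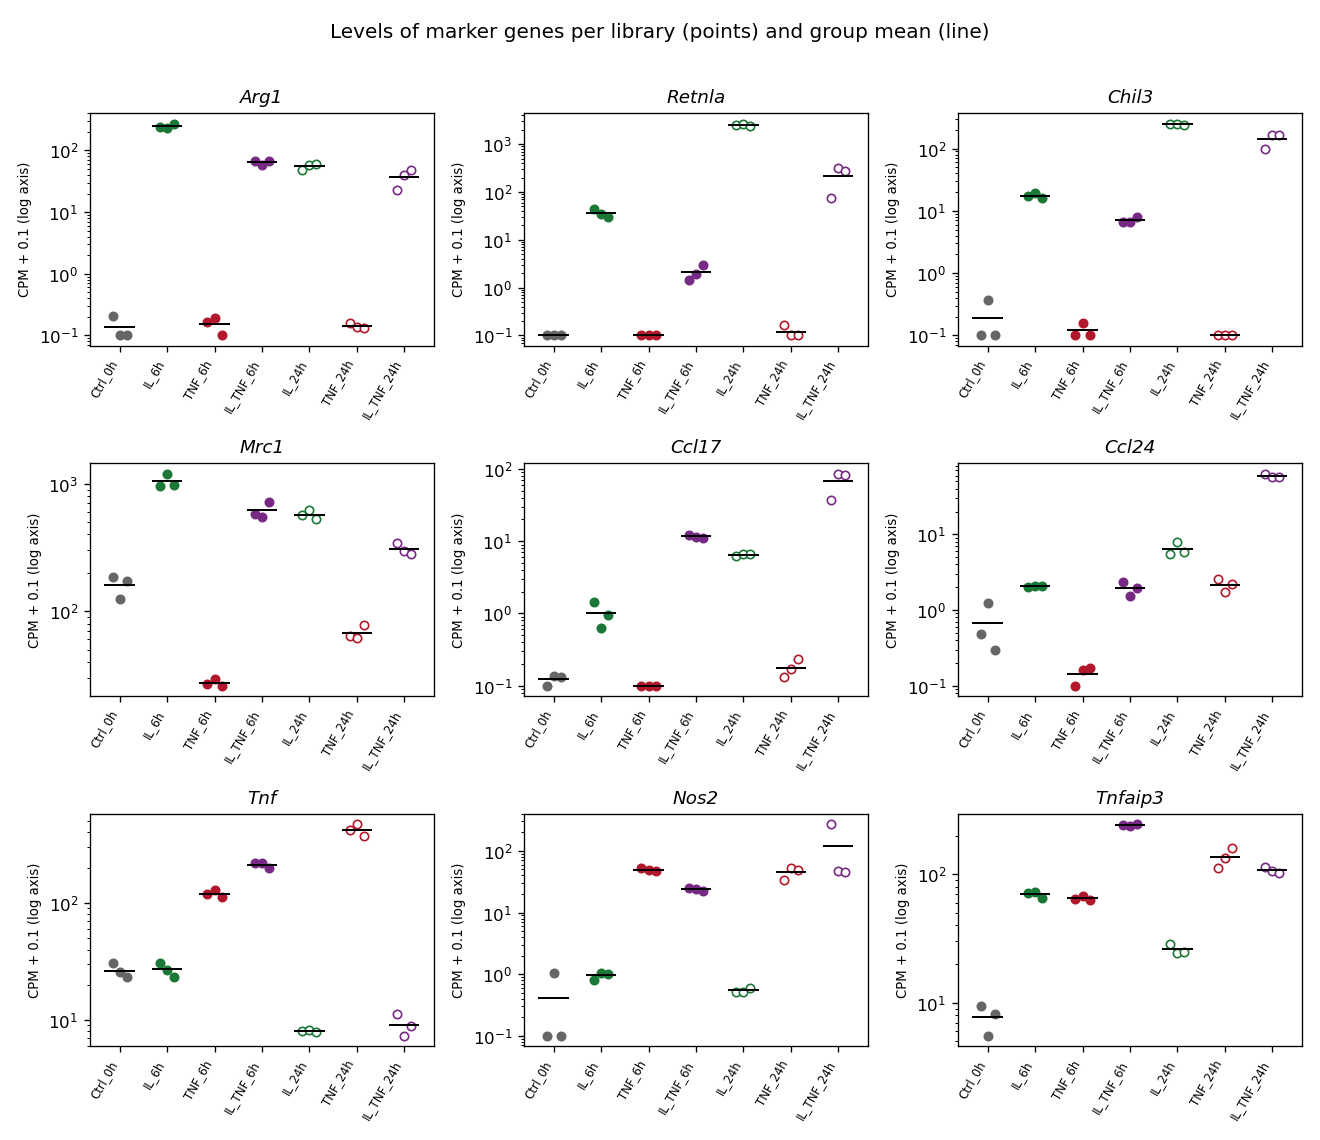
Each panel shows 1 gene, with the CPM plus 0.1 on a log axis for each library (points, filled at 0 h and 6 h, open at 24 h) and the group means (lines). Arg1, Retnla and Chil3 were high in the groups with IL, where Retnla reached 2507 CPM in IL_24h and 220.5 CPM in IL_TNF_24h, and Tnf was highest in TNF_24h at 419.7 CPM.

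TNF_6h was compared with Ctrl_0h to find the early response to TNF alone, together with 6 h in culture. Both groups lay in the same set of libraries. Acod1, the enzyme that makes itaconate, rose from 1.07 ± 0.0372 to 539 ± 18.7 CPM (log2 fold change 8.98 ± 0.26). The acute-phase gene Saa3 rose from 2.35 ± 1.18 to 2172 ± 218 CPM, the complement gene C3 from 22.9 ± 4.72 to 3670.4 ± 171 CPM and the chemokine gene Ccl5 from 1.93 ± 0.594 to 954 ± 142 CPM. Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960226), rose from 0.316 ± 0.547 to 49.7 ± 3.35 CPM, and Tnf itself (ENSMUSG00000024401, chromosome 17, 35199367 to 35202007) from 26.3 ± 3.90 to 120.2 ± 9.36 CPM. Large rises were also seen in the complement gene Cfb, at 1369.8 (245 to 54146) times its level in Ctrl_0h, the class I gene H2-M2 (log2 fold change 9.29 ± 0.35), haptoglobin (Hp, 8.69 ± 0.63), the formyl peptide receptor gene Fpr2 (7.22 ± 0.39) and the metalloproteinase gene Mmp14 (7.21 ± 0.53). When replicate 2 of Ctrl_0h was left out, Nos2 and Cfb rose from 0 counts, Hp by 11.52 and Mmp14 by 8.44. The transporter gene Slco2b1 fell from 12.3 ± 2.82 to 0.0905 ± 0.0784 CPM, Dmpk from 51.0 ± 9.80 to 1.598 ± 0.138 CPM and Mrc1 from 161 ± 31.5 to 27.3 ± 1.65 CPM. Ighm (-5.60), Mxd3 (-5.25) and Nanos1 (-5.22) fell, as did Esco2, Sapcd2 and Mns1 (-4.67, -4.65 and -4.45). The falls of Sdk1 and Sox12 rested in large part on replicate 2 of Ctrl_0h, with 30.5 and 42.3 CPM there.

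Il1b rose by 4.28 (5.34 without replicate 1 of Ctrl_0h), Tnfaip3 by 3.09, Nfkbia by 2.31 and Tnfrsf1b by 1.86 on the log2 scale after 6 h of TNF, and Ccl24 changed by -3.60. Retnla had 0 counts in both groups, and Arg1 (adjusted p 0.823), Chil3 (0.325), Ccl17 (0.316), Socs1 (0.0851), Socs3 (0.778) and Il4ra (0.825) were not called. Without replicate 2 of Ctrl_0h, Socs1 (log2 fold change 1.58) and Socs3 (0.95) were called as raised. 6117 genes were called, 2928 raised and 3189 lowered. All 33 interferon-stimulated genes rose, also over the list alone (adjusted p = 7.67e-23, adjusted p = 0.153 with an estimated correlation), with 9.36 ± 1.03 for the guanylate-binding protein gene Gbp5. Of 33 NF-kB genes 27 rose (28 over the list alone; adjusted p 4.55e-18), and of 11 MHC class II genes 9 rose (10 over the list alone; adjusted p 1.74e-09), H2-Aa by 3.86 ± 0.17. All 30 cell cycle genes fell (adjusted p = 3.41e-17, adjusted p = 0.201 with an estimated correlation). In the list of cytokine receptors 12 of 17 rose, Il13ra1 by 2.16 (adjusted p = 4.59e-07, adjusted p = 0.199 with an estimated correlation). Lysosomal genes rose in 10 of 25 cases (12 over the list alone), with adjusted p = 4.83e-04 and adjusted p = 0.445 with an estimated correlation. Efflux genes rose in 7 of 11 cases, the transporter gene Abca1 by 1.64 ± 0.17 (adjusted p = 0.00714, adjusted p = 0.233 with an estimated correlation). The alternative activation list had 6 genes raised and 10 lowered and was not called (adjusted p 0.359), nor was the respiratory chain (0.934).

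TNF_24h was compared with Ctrl_0h to find the later response to TNF alone, together with 24 h in culture. The chemokine gene Cxcl10 rose from 5.07 ± 2.20 to 2892 ± 297 CPM and its relative Cxcl9 from 0.0621 ± 0.00760 to 27.3 ± 6.79 CPM. Cxcl11 had 0 counts in Ctrl_0h and 22.4 ± 2.87 CPM in TNF_24h, at least 725-fold, and Serpina3f, 1 of a family of similar protease inhibitor genes, was raised at least 366-fold. Acod1 reached 1514 ± 165 CPM (log2 fold change 10.47 ± 0.27) and Tnf 419.7 ± 48.99 CPM (3.99 ± 0.16). The activation marker Cd69 (7.90 ± 0.47), the chemokine genes Ccl12 (7.86 ± 0.76) and Ccl5 (7.59 ± 0.30), Serpina3g (7.41 ± 0.66, and 8.62 without replicate 3 of Ctrl_0h) and H2-M2 (7.29 ± 0.33) rose as well. Slco2b1 (-5.18 ± 0.72), Dmpk (-4.46 ± 0.25) and Mrc1 (-1.25 ± 0.15) fell. The 8 other genes among the 10 largest falls were Onecut3, Mtcl1, Reg2, Sox12, Nat8l, Sox4, Rapgefl1 and Apc2, and all of them rested in large part on replicate 2 of Ctrl_0h. Without that library Onecut3 had a log2 fold change of -6.04 and was not called.

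Socs1 rose to 95.04 ± 6.72 CPM and Socs3 to 86.4 ± 3.48 CPM after 24 h of TNF. Nos2 rose to 45.0 ± 10.2 CPM. Tnfaip3 rose by 4.16, Nfkbia by 2.99, Il1b by 3.41 (4.47 without replicate 1 of Ctrl_0h), Tnfrsf1b by 1.71 and Ccl24 by 1.87 on the log2 scale. With single libraries left out the rise of Ccl24 lay between 1.49 and 2.80. Arg1 (adjusted p 0.964), Retnla (0.513), Chil3 (0.0759), Ccl17 (0.257) and Il4ra (0.980) were not called. In a fit of these 6 libraries alone Ccl24 was not called (1.81). 7054 genes were called, 3258 raised and 3796 lowered. All 33 interferon-stimulated genes rose (adjusted p = 2.98e-24, adjusted p = 0.142 with an estimated correlation), as did 31 of 33 NF-kB genes (adjusted p 8.02e-27) and 13 of 15 signalling feedback genes (adjusted p 8.95e-10). Of 30 cell cycle genes 15 fell (16 over the list alone; adjusted p = 3.69e-04, adjusted p = 0.600 with an estimated correlation), and of 18 cholesterol synthesis genes 13 rose (adjusted p = 1.84e-05, adjusted p = 0.209 with an estimated correlation). In alternative activation 9 genes rose and 9 fell without a call of the list (10 and 9 over the list alone; adjusted p 0.824), and the chemokine gene Ccl22 of that list rose by 5.68 ± 0.25.

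IL_TNF_6h was compared with IL_6h to ask how TNF changes the early response to IL-4 and IL-13. Both groups lay in the same set. Retnla fell from 36.7 ± 7.31 to 2.01 ± 0.758 CPM (log2 fold change -4.18 ± 0.45), Arg1 from 248 ± 20.1 to 65.0 ± 5.35 CPM (-1.93 ± 0.23), Chil3 from 17.5 ± 1.66 to 6.91 ± 0.810 CPM (-1.34 ± 0.27) and Mrc1 from 1043 ± 128 to 618 ± 93.0 CPM (-0.76 ± 0.15). Ccl17, by contrast, rose from 0.912 ± 0.413 to 11.6 ± 0.544 CPM (3.66 ± 0.33). Tnf rose from 26.9 ± 3.76 to 212 ± 12.9 CPM, Nos2 from 0.862 ± 0.136 to 23.6 ± 1.51 CPM and Socs3 from 9.62 ± 1.84 to 79.4 ± 19.0 CPM. The adhesion molecule gene Vcam1 rose from 0.425 ± 0.219 to 22.8 ± 2.30 CPM, and the receptor gene Clec4e, which senses mycobacterial lipids, from 45.9 ± 4.95 to 903 ± 120.4 CPM. The actin-bundling protein gene Fscn1 (log2 fold change 5.04 ± 0.72), the chemokine genes Cxcl3 (4.82 ± 0.60) and Cxcl10 (4.06 ± 0.58), Lad1 (4.55 ± 0.40), the ephrin gene Efna2 (4.39 ± 0.57), Apol7c (4.25 ± 0.32) and the prostaglandin synthase gene Ptges (4.12 ± 0.30) completed the 10 largest rises. Among the largest falls were thrombomodulin (Thbd, -3.27 ± 0.24), Hpgd (-3.05 ± 0.23), Scn3a (-3.30 ± 0.34) and Rasgrp3 (-2.75 ± 0.16), beside Rnf150, Msx3, Zfyve28, Eps8 and Cd300lf with log2 fold changes between -3.46 and -2.64. The call of Msx3 ended when any of these 6 libraries other than replicate 2 of IL_6h was left out (log2 fold changes between -3.18 and -2.89).

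Il1b rose by 2.89, Tnfaip3 by 1.79, Nfkbia by 1.65 and Tnfrsf1b by 0.75 on the log2 scale when TNF was added for 6 h. Ccl24 (adjusted p 0.947), Socs1 (0.248) and Il4ra (0.846) were not called. 2193 genes were called, 1105 raised and 1088 lowered. Of 29 alternative activation genes 12 fell and 4 rose, with the same counts over the list alone (adjusted p = 0.0115, adjusted p = 0.203 with an estimated correlation). The lectin gene Clec10a fell by this measure (-2.45 ± 0.13) and Ccl22 rose (3.20 ± 0.20). Of 33 NF-kB genes 28 rose (31 over the list alone; adjusted p 3.41e-38), and of 33 interferon-stimulated genes 25 rose (29 over the list alone; adjusted p = 1.77e-18, adjusted p = 0.208 with an estimated correlation). 7 of 11 MHC class II genes rose (9 over the list alone; adjusted p = 3.65e-06, adjusted p = 0.0802 with an estimated correlation), and 9 of 15 feedback genes (adjusted p 4.24e-07). Macrophage identity genes were not called as a list (adjusted p 0.768), though the haemoglobin scavenger receptor Cd163 fell (-2.39 ± 0.38). The respiratory chain (0.613), glycolysis (0.637) and lysosome (0.256) lists were not called.

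IL_TNF_24h was compared with IL_24h to ask how TNF changes the later response to IL-4 and IL-13. Retnla fell from 2507 ± 161 to 220.5 ± 129.6 CPM (log2 fold change -3.51 ± 0.41) and Mrc1 from 573 ± 45.5 to 308 ± 32.0 CPM (-0.90 ± 0.15), while Arg1 (-0.57 ± 0.22, adjusted p 0.122) and Chil3 (-0.77 ± 0.26, 0.0631) were not called. Arg1 was called as lowered without replicate 3 of IL_TNF_24h (-0.81) and Chil3 with the DESeq2 Wald test (-0.78). Ccl17 rose from 6.38 ± 0.175 to 67.9 ± 26.8 CPM and Ccl24 from 6.34 ± 1.30 to 59.1 ± 3.07 CPM. Nos2 rose from 0.445 ± 0.0519 to 120.1 ± 129 CPM, with 269, 46.2 and 44.6 CPM in the 3 replicates. H2-M2 rose to 587 ± 236 CPM, the metalloproteinase gene Mmp9 to 86.6 ± 36.9 CPM, Apol7c to 359 ± 172 CPM and Ccl5 to 139 ± 46.7 CPM. The other large rises were those of Gbp5 (log2 fold change 6.66 ± 0.55), Lad1 (5.80 ± 0.45), Mmp14 (5.74 ± 0.50), the chemokine gene Ccl8 (5.71 ± 0.72) and Serpina3g (5.10 ± 0.57). Without replicate 1 of IL_TNF_24h, Nos2 was at 6.66 and Ccl8 at 4.28. Cd5l, a secreted protein that binds lipids, fell from 59.4 ± 6.41 to 8.68 ± 2.65 CPM and the endocytic adaptor gene Dab2 from 169.8 ± 12.2 to 31.2 ± 0.611 CPM. Scn3a (-3.19 ± 0.34), Ear2 (-2.66 ± 0.46) and Rasgrp3 (-2.38 ± 0.15) fell, as did Cd300lg, Hmga2, Qpct and Nes with log2 fold changes between -2.73 and -2.13. With the DESeq2 Wald test Ear2 was not called (-2.67), and in a fit of these 6 libraries alone Nes was not called (-2.12).

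Tnfaip3 rose by 2.06, Nfkbia by 1.36 and Socs3 by 1.44 on the log2 scale when TNF was present for 24 h, and the last call ended without replicate 3 of IL_24h (1.27). Tnf (adjusted p 0.585), Il1b (0.937), Socs1 (0.238), Il4ra (0.191) and Tnfrsf1b (0.562) were not called. 1731 genes were called, 940 raised and 791 lowered, and the number lowered was 511 without replicate 1 of IL_24h and 508 without replicate 2. Of 29 alternative activation genes 8 rose and 9 fell (8 and 11 over the list alone), and the list was not called (adjusted p 0.924). 32 of 33 interferon-stimulated genes rose, the GTPase gene Iigp1 by 8.00 ± 1.23, by 5.68 without replicate 1 of IL_TNF_24h and from 0 counts without replicate 1 of IL_24h (33 genes over the list alone; adjusted p = 8.95e-31, adjusted p = 0.0879 with an estimated correlation). 24 of 33 NF-kB genes (26 over the list alone; adjusted p 2.98e-24) and 8 of 11 MHC class II genes (adjusted p 4.46e-09) rose. Of 30 cell cycle genes 13 fell (27 over the list alone; adjusted p = 1.87e-14, adjusted p = 0.238 with an estimated correlation). Tpx2 of the mitotic spindle had a log2 fold change of -1.13 ± 0.21. Respiratory chain genes rose in 11 of 37 cases (21 over the list alone; adjusted p = 5.20e-11, adjusted p = 0.249 with an estimated correlation), Cox5a by 0.72 ± 0.15. Cholesterol synthesis genes rose in 5 of 18 cases (7 over the list alone; adjusted p = 1.04e-05, adjusted p = 0.201 with an estimated correlation).

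**Figure D3:**
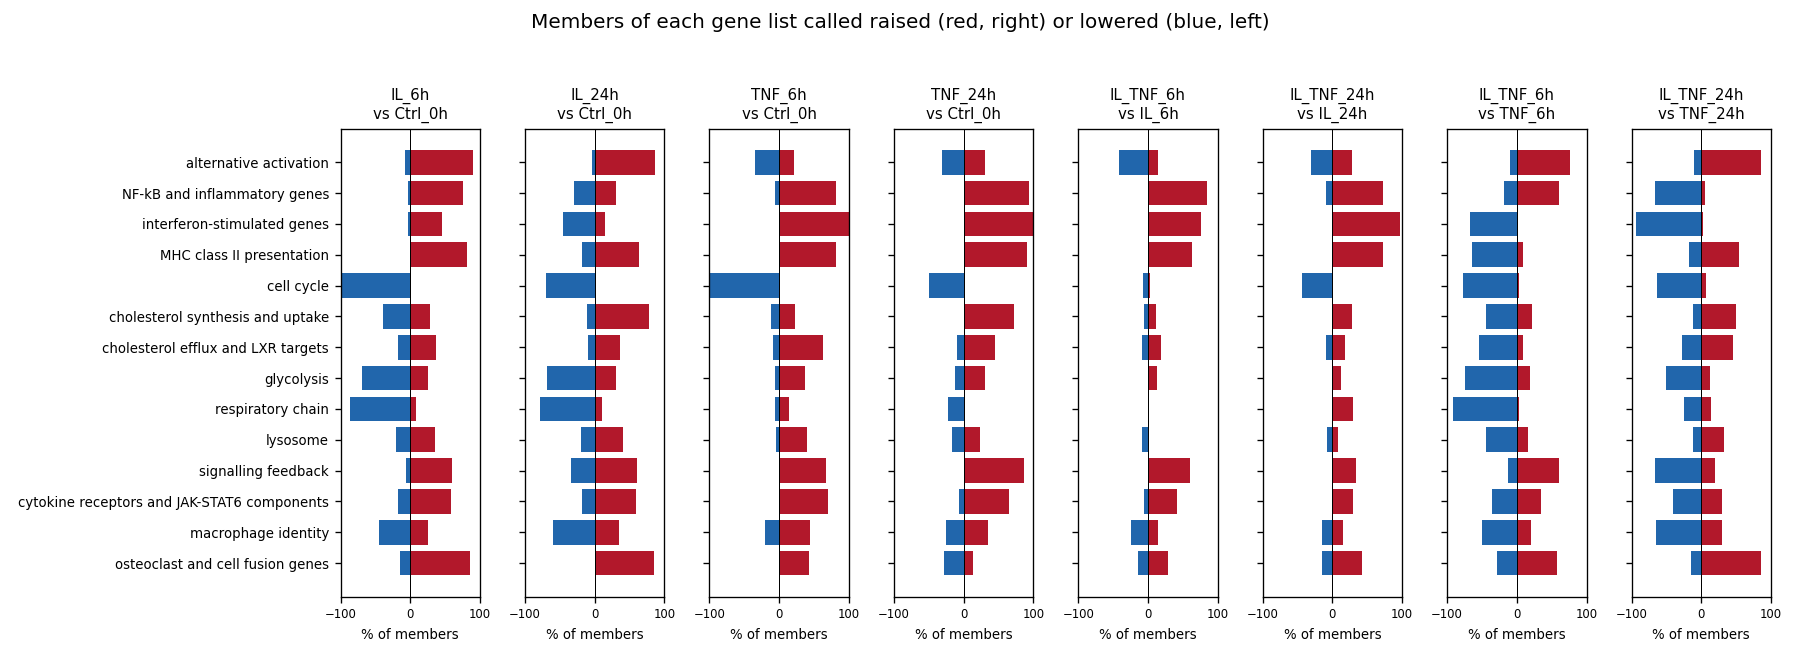
Each panel shows 1 comparison, with bars for the percentage of each gene list that was raised (to the right) or lowered (to the left). TNF raised all 33 interferon-stimulated genes against Ctrl_0h at both times, and IL raised 26 of 29 alternative activation genes at 6 h.

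Genes raised by IL at least 2-fold were followed when TNF was added. At 6 h there were 3048 such genes, of which 253 were lowered by TNF, or 8.30% (95% Wilson interval 7.37 to 9.33), while 362 were raised further (11.9%) and 2433 were not called. Among all tested genes 6.98% were lowered. At 24 h there were 2850 such genes, of which 165 were lowered, or 5.79% (4.99 to 6.71), 216 raised further (7.58%) and 2469 not called, beside 5.08% lowered among all tested genes. At both times 56 genes were lowered and 106 raised further. The genes were chosen by a fit that shares the IL libraries with the TNF comparison, and when the genes raised at the other time were followed the lowered shares were 9.75% at 6 h and 4.13% at 24 h and the shares raised further 9.26% and 11.3%, so that at 6 h the order of the 2 shares turned. The share at 6 h was 5.37% without replicate 2 of IL_TNF_6h, and that at 24 h was 3.63% without replicate 2 and 3.90% without replicate 1 of IL_24h. Fewer genes were lowered among all tested in these fits, 741 against 1088 at 6 h and 508 and 511 against 791 at 24 h. The Wilson intervals take the genes as independent and do not cover this dependence on single libraries.

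The effects of TNF without and with IL overlapped. At 6 h, 800 genes rose in both, which was 72.4% of the genes raised by TNF in the presence of IL, against 208 expected if the lists were independent, and 76 rose without IL and fell with it. For falls the shared number was 551 against 223 expected. At 24 h, 677 genes rose in both against 197 expected, and 511 fell in both against 193 expected. These pairs share no libraries. In the presence of IL, 524 genes rose with TNF at both times against 66.7 expected, and 398 fell at both against 55.2.

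IL_TNF_6h was compared with TNF_6h to ask how IL-4 and IL-13 change the early response to TNF. Saa3 fell from 2172 ± 218 to 73.6 ± 12.7 CPM and haptoglobin from 53.0 ± 7.43 to 0.650 ± 0.271 CPM. Isg20, an interferon-induced exonuclease, fell from 173 ± 8.95 to 10.5 ± 1.86 CPM. Arg1 rose from 0.0522 ± 0.0466 to 65.0 ± 5.35 CPM (log2 fold change 10.15 ± 0.43), Slc7a2 from 2.77 ± 0.466 to 775 ± 133 CPM and Mrc1 from 27.3 ± 1.65 to 618 ± 93.0 CPM. Ccl17 rose at least 356-fold and Retnla at least 63.0-fold, both from 0 counts in TNF_6h, and Chil3 stood at 321 (88.5 to 2652) times its level there. The imprinted gene Peg10 (10.70 ± 0.60), Tmem26 (9.05 ± 0.36), neuregulin 1 (Nrg1, 7.75 ± 0.65), Rab11fip4 (7.57 ± 1.06), the integrin gene Itgb8 (7.50 ± 0.91) and Lad1 (6.91 ± 0.47) rose, as did Ifi202b, which had 0 counts in TNF_6h. Tmem26 was at 10.18 without replicate 1 of TNF_6h and Nrg1 at 9.81 without replicate 3, where Itgb8 rose from 0 counts. Ifitm6 (-4.34 ± 0.18), Slfn1 (-4.27 ± 0.75), Cx3cr1 (-4.22 ± 0.43) and Apol9a (-4.13 ± 0.61) fell, with Pilrb1, Fcrl1 and Pilrb2 between -4.09 and -3.81.

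Tnf was higher with all 3 cytokines than with TNF alone at 6 h, at 212 ± 12.9 against 120.2 ± 9.36 CPM. Ccl24 rose by 5.32, Il1b by 1.64, Tnfaip3 by 1.90, Socs1 by 2.11, Socs3 by 3.04 and Tnfrsf1b by 1.15 on the log2 scale. Nos2 (adjusted p 0.0990), Nfkbia (0.611) and Il4ra (0.128) were not called, though Nos2 was called as lowered in a fit of these 6 libraries alone (-1.06). 8903 genes were called, 4625 raised and 4278 lowered, in a comparison that crosses sets. 22 of 29 alternative activation genes rose (23 over the list alone; adjusted p 2.09e-09). 22 of 33 interferon-stimulated genes fell and 0 rose (24 fell over the list alone; adjusted p = 1.10e-04, adjusted p = 0.599 with an estimated correlation), and 20 of 33 NF-kB genes rose (21 over the list alone; adjusted p = 0.00250, adjusted p = 0.156 with an estimated correlation). 34 of 37 respiratory chain genes fell (adjusted p = 1.30e-08, adjusted p = 0.306 with an estimated correlation), as did 12 of 16 glycolysis genes (adjusted p = 0.00250, adjusted p = 0.489 with an estimated correlation).

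IL_TNF_24h was compared with TNF_24h to ask how IL-4 and IL-13 change the later response to TNF. Tnf fell from 419.7 ± 48.99 to 9.05 ± 2.01 CPM (log2 fold change -5.54 ± 0.18) and Cxcl10 from 2892 ± 297 to 5.68 ± 6.89 CPM (-9.01 ± 0.71). Cd69 fell from 104 ± 11.2 to 0.563 ± 0.707 CPM and Ch25h, an enzyme that makes an oxysterol, from 62.5 ± 12.1 to 0.875 ± 0.0728 CPM. The lipase gene Lipg (-8.18 ± 0.40), Cxcl11 (-7.98 ± 0.63), Fpr2 (-7.21 ± 0.39), Ighm (-6.44 ± 0.38), Hpgd (-6.31 ± 0.31) and Trim30b (-6.27 ± 0.49) fell. Without replicate 1 of IL_TNF_24h, Cxcl10 was at -10.75 and Cd69 at -9.38, and Cxcl11 fell to 0 counts. Chil3 had 0 counts in TNF_24h and 144 ± 40.2 CPM in IL_TNF_24h, at least 4466-fold. Cyp1b1, a cytochrome that oxidises steroids and foreign compounds, also went from 0 counts to 142 ± 61.1 CPM, at least 4468-fold. Rnase2a rose at least 5764-fold and Il31ra at least 508-fold, and the kinase gene Dclk1 rose at least 355-fold. Retnla stood at 10487 (2903 to 86596) times its level in TNF_24h and Aldh1a2, which makes retinoic acid, at 3427 (1172 to 16619.9) times. The Y-linked genes and Xist again marked the set.

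Arg1 rose by 9.63, Mrc1 by 2.18, Ccl17 by 9.73, Ccl24 by 4.84 and Tnfrsf1b by 0.55 on the log2 scale, all against 24 h of TNF. Socs3 (-3.39 ± 0.35), Il1b (-2.79 ± 0.46, and -3.85 without replicate 3 of IL_TNF_24h) and Nfkbia (-2.09 ± 0.12) fell. Nos2 was called as raised (1.41 ± 0.54, adjusted p 0.0326), but without replicate 1 of IL_TNF_24h its log2 fold change was -0.00250. Tnfaip3 (adjusted p 0.0541), Socs1 (0.111) and Il4ra (0.739) were not called, though Tnfaip3 was called as lowered without replicate 1 of IL_TNF_24h (-0.40) or replicate 1 of TNF_24h (-0.46). 8771 genes were called, 4543 raised and 4228 lowered. 22 of 33 NF-kB genes fell (25 over the list alone; adjusted p 6.70e-10), with -5.81 ± 0.14 for Cxcl2, and 31 of 33 interferon-stimulated genes fell (adjusted p = 7.56e-14, adjusted p = 0.260 with an estimated correlation). 10 of 15 feedback genes fell, with -5.33 ± 0.41 for Il10 (-6.39 without replicate 1 of IL_TNF_24h), while Cish rose by 6.27 ± 0.51 (adjusted p = 7.32e-04, adjusted p = 0.104 with an estimated correlation). 25 of 29 alternative activation genes (adjusted p 9.80e-12) and 6 of 7 osteoclast genes (2.70e-04) rose.

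The combination was compared with Ctrl_0h to find its whole effect. At 6 h Olr1, a receptor for oxidised lipoprotein, rose at least 392-fold from 0 counts, and Apol7c went from 0.0854 ± 0.105 to 231 ± 9.47 CPM. Arg1 (log2 fold change 10.52 ± 0.44), Acod1 (10.30 ± 0.27) and H2-M2 (9.63 ± 0.35) rose, with Tnf at 3.01, Nos2 at 6.32, Il1b at 5.92 (6.98 without replicate 1 of Ctrl_0h) and Socs3 at 3.18. At 24 h Retnla rose at least 7447-fold, Gbp5 at least 544-fold and Chil3 by 10.71 ± 0.47, and Hpgd went from 131 ± 12.6 to 0.135 ± 0.0363 CPM. Id3, an inhibitor of differentiation, changed by -7.09 ± 0.26 and Tnf by -1.54 ± 0.15. The rises of Arg1, Nos2 and Chil3 each rest on counts in a single library of Ctrl_0h, and their size is open. The numbers called were 10478 at 6 h (5269 raised and 5209 lowered) and 10175 at 24 h (5148 raised and 5027 lowered). Without replicate 2 of Ctrl_0h, Socs3 was called as raised at 24 h (0.73), against -0.09 ± 0.33 with it (adjusted p 0.823).

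Each treatment was compared between 24 h and 6 h to find what changed with time. Under IL, Retnla rose by 6.09 ± 0.47, Chil3 by 3.81 ± 0.29 and Ocstamp by 5.60 ± 0.34, while Arg1 (-2.17 ± 0.23), Irf7, a regulator of interferon genes (-5.41 ± 0.55), and Id3 (-5.23 ± 0.22) fell. Under TNF, Ccl22 rose from 1.48 ± 0.0905 to 32.2 ± 1.22 CPM, Ccl2 from 7.82 ± 0.517 to 86.1 ± 5.08 CPM, Tnf by 1.80 ± 0.15 and Socs3 by 3.16 ± 0.34, and Saa3 fell from 2172 ± 218 to 300.5 ± 96.1 CPM. With all 3 cytokines, Mgl2, a lectin of alternative activation, rose from 3.27 ± 0.526 to 170.0 ± 70.3 CPM and Ccl24 by 4.99 ± 0.33, while Tnf fell from 212 ± 12.9 to 9.05 ± 2.01 CPM and Il1b from 17.1 ± 2.54 to 0.426 ± 0.385 CPM. Between times 3743 genes were called under IL, 3675 under TNF and 4474 under the combination. All 30 cell cycle genes rose under IL (adjusted p = 1.18e-21, adjusted p = 0.142 with an estimated correlation), and 28 of 33 NF-kB genes fell under IL (29 over the list alone; adjusted p 8.51e-19) and 28 under the combination (1.92e-18), while 20 rose under TNF (22 over the list alone; adjusted p 2.09e-09). Cholesterol synthesis genes rose in 17 of 18 cases under the combination (18 over the list alone; adjusted p 7.37e-13). The comparisons under IL and under the combination cross sets, which the comparison under TNF does not.

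The interaction was the effect of TNF with IL, taken against IL at the same time, minus its effect without IL, taken against Ctrl_0h. The second carries the time in culture and the first does not, so a change with time alone enters the interaction with the opposite sign. At 6 h Saa3 had an interaction of -8.98 ± 0.44 and Ccl5 of -7.36 ± 0.36 on the log2 scale. TNF took Ccl5 from 1.93 ± 0.594 to 954 ± 142 CPM without IL, and from 26.2 ± 2.64 to 78.0 ± 10.6 CPM with IL. Socs3 had a positive interaction of 2.91 ± 0.47 and Mrc1 of 1.80 ± 0.21. At 24 h Tnf had an interaction of -3.80 ± 0.22, Acod1 of -5.64 ± 0.29 and the chemokine gene Cxcl2 of -4.72 ± 0.18. 2866 genes were called at 6 h (1444 raised and 1422 lowered) and 3758 at 24 h (1812 and 1946). The numbers raised and lowered were 1190 and 1877 at 6 h without replicate 2 of IL_6h, 1181 and 1828 without replicate 3 of IL_TNF_6h, and 1043 and 1783 at 24 h without replicate 2 of IL_24h. 28 of 30 cell cycle genes had a positive interaction at 6 h, Mki67 of 4.37 ± 0.45 (29 genes over the list alone; adjusted p = 1.92e-17, adjusted p = 0.201 with an estimated correlation), and 8 of 11 MHC class II genes a negative one (9 over the list alone; adjusted p 7.02e-08). All 30 cell cycle genes fell against Ctrl_0h at 6 h under IL, under TNF and under all 3 cytokines, while 2 fell and 1 rose when TNF was added to IL, and a fall with time alone gives the same positive interaction. At 24 h 25 of 33 NF-kB genes (adjusted p 1.01e-19) and 12 of 15 feedback genes (1.81e-09) had a negative interaction. Differences between sets enter the effect with IL and the effect without it separately and cancel only where they are additive.

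The effect of TNF in the presence of IL was also compared between 24 h and 6 h. Ccl5 changed in it by 4.15 ± 0.33 and Ccl24 by 3.30 ± 0.43, and Tnf by -2.79 ± 0.21. Icosl, a ligand of T cell costimulation, changed by -3.38 ± 0.24. Of 573 genes called, 295 were higher and 278 lower in this effect at 24 h, and between 343 and 375 genes were called without replicate 3 of IL_6h or any 1 library of IL_24h, against 943 with the DESeq2 Wald test and 992 with the 3 libraries left out. Of 29 alternative activation genes 9 were raised (13 over the list alone; adjusted p = 3.75e-04, adjusted p = 0.0657 with an estimated correlation), and of 33 NF-kB genes 7 were lowered (9 over the list alone; adjusted p 1.51e-05).

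Marker genes of other cell types were summed in each group. Macrophage identity genes summed to 34442 ± 2734 CPM in Ctrl_0h, 53134 ± 2285 CPM in TNF_6h and 15069 ± 640 CPM in IL_TNF_24h. The highest group sums of the other markers were 19.6 ± 0.43 CPM for neutrophils in IL_TNF_24h, 32.0 ± 14.6 CPM for eosinophils, mast cells and basophils in IL_TNF_24h, 5.80 ± 5.18 CPM for fibroblasts in IL_6h, 30.2 ± 1.75 CPM for T and NK cells in TNF_6h, 3.94 ± 5.31 CPM for B cells in Ctrl_0h, 14.7 ± 6.66 CPM for dendritic cells in IL_TNF_24h and 0.518 ± 0.84 CPM for erythroid cells. The B cell sum was 10.1 CPM in replicate 2 of Ctrl_0h and 0.685 CPM in the lowest library of that group, beside 3.68 ± 0.61 CPM in IL_TNF_6h, and the fibroblast sum was 11.8 CPM in replicate 2 of IL_6h and 2.45 CPM in the lowest, with 8.58 CPM in replicate 3 of IL_TNF_6h. Most of the T and NK cell sum came from Cd4, a T cell coreceptor, and most of the dendritic cell sum from the transcription factor gene Zbtb46. In IL_TNF_24h most of the eosinophil, mast cell and basophil sum came from Siglec5 (13.3, 38.1 and 39.5 CPM). Most of the neutrophil sum there came from Mmp8 (16.7, 13.8 and 14.1 CPM). Cxcr2 of the neutrophil list had 2.167, 5.093 and 5.296 CPM in IL_TNF_24h and at most 0.516 CPM in any library of the other groups. Epx, Mcpt8 and Ly6g, picked from these lists, had 0 CPM in IL_TNF_24h.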

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

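All tests of the 3 library patterns below, and the count of splits for IL_6h against Ctrl_0h, were chosen after the result was seen. The values below come from tests of a difference between effects and were kept because that difference was called. In the interactions the effect of TNF without IL is taken against untreated cells of 0 h, so these values also carry the time in culture, and the groups do not show how much of them belongs to TNF. A fitted value of a gene with 0 counts in a group, such as Serpina3f, Cyp1b1, Dclk1 or Olr1, depends on the prior count and is no bound.

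At 6 h, 2866 genes were called for the interaction. It was 5.08 for Hmgb3, 4.98 for Sapcd2 and 4.89 for Kif4 on the log2 scale. It was 5.09 for Efna2 and 4.92 for Fscn1, which were 3.33 and 2.16 without replicate 2 of Ctrl_0h, and 6.42 for Ighm. Values of 6.60 for Prob1, 5.41 for Mycl, 5.23 for Rab11fip4 and 5.12 for Mmp25 ended as calls without replicate 2 of Ctrl_0h, where they were 2.90, 1.47, 1.57 and 0.0533. Negative values were -9.03 for Cfb, which had all its Ctrl_0h counts in replicate 2, -8.98 for Saa3, -7.64 for Hp (-10.47 without that library), -5.46 for C3, -6.41 for Ms4a4c, -5.93 for Slfn4, -5.73 for Slfn1, -5.77 for H2-M2, -5.28 for Il18bp and -7.36 for Ccl5. Of the marker genes, positive values were 1.80 for Mrc1, 3.52 for Ccl24, 0.79 for Tnf and 2.91 for Socs3, and negative values were -1.30 for Tnfaip3, -0.67 for Nfkbia and -1.11 for Tnfrsf1b.

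At 24 h, 3758 genes were called for the interaction. Values were -4.72 for Cxcl2, -5.37 for Cxcl9 and -4.96 for Cxcl10, of which Cxcl9 was not called without replicate 1 of IL_24h (-4.52). Other negative values were -9.87 for Serpina3f, -6.26 for Lipg, -5.64 for Acod1, -5.57 for Tnfsf10, -5.01 for Tarm1, -4.85 for Cd69 and -4.51 for Olr1. Of these, Cd69 was not called without replicate 3 of IL_24h (-4.65), and without replicate 1 of IL_TNF_24h Cd69 was at -6.69, Cxcl10 at -6.75 and Serpina3f at -10.95. Olr1 was not called without any of 8 of the 12 libraries (-4.14 without replicate 3 of TNF_24h). Among the marker genes the values were -3.80 for Tnf, -3.24 for Il1b (-4.31 without replicate 3 of IL_TNF_24h), -2.11 for Tnfaip3, -1.63 for Nfkbia, -2.67 for Socs1, -1.86 for Socs3 and -1.56 for Tnfrsf1b, with 1.35 for Ccl24, which was 0.42 and not called without replicate 2 of Ctrl_0h and not called without any of 9 of the 12 libraries. Positive values were 9.49 for Reg2, 8.52 for Dclk1, 7.90 for Cyp1b1, 7.47 for Sox12, 6.31 for Aldh1a2, 5.76 for Nr4a3, 5.33 for Sema6c, 5.31 for Rapgefl1 and 4.96 for Zbtb46. Without replicate 2 of Ctrl_0h, the calls ended for Reg2 (3.12), Dclk1 (1.81), Cyp1b1 (6.18), Aldh1a2 (-0.0769), Rapgefl1 (1.65) and Zbtb46 (1.42), and the values of Sox12, Nr4a3 and Sema6c were 4.27, 3.52 and 3.43.

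Between 6 h and 24 h, 573 genes were called for a change of the TNF effect in the presence of IL. Higher values at 24 h were 4.46 for Ly6a, 4.45 for Ms4a4c, 4.23 for Ccl8, 4.15 for Ccl5, 3.98 for Irf7 and 3.76 for Serpina3g, and further rises were 4.65 for Nrg1, 3.81 for Ccr7, 3.54 for Nr4a3 and 3.40 for P2rx5. Without replicate 1 of IL_TNF_24h Ly6a was at 2.82, Ms4a4c at 1.77, Ccl8 at 2.80 and Irf7 at 2.46. The interferon list as a whole had 4 of 33 genes raised (adjusted p = 0.00284, adjusted p = 0.696 with an estimated correlation) and without replicate 2 of Ctrl_0h, replicate 3 of TNF_6h and replicate 1 of IL_TNF_24h pointed down without a call (adjusted p 0.216). Lower values were -2.79 for Tnf, -2.73 for Il1b (-3.79 without replicate 3 of IL_TNF_24h), -2.49 for Nlrp3, -3.38 for Icosl and -3.18 for Ptges, and -3.75 for Fzd1, -2.72 for Cd5l, -2.63 for Ctnnd2, -2.58 for Phgdh and -2.42 for Itga4. Of the marker genes, Arg1 had 1.36, Ccl24 3.30 and Tnfrsf1b -0.60. The calls of Ms4a4c, Ccr7, Nr4a3, Fzd1, Il1b, Arg1 and Tnfrsf1b ended without at least 1 of the libraries, with values of 3.51 for Ccr7 without replicate 1 of IL_TNF_24h and 1.13 for Arg1 without replicate 3.

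Other splits of the libraries were counted for each number of genes called, in fits of the libraries compared alone. For the 13 comparisons of a pair of groups the 6 libraries allow 10 splits, too few for a share under 0.05, and in each 1 split, the real one, reached the real number. The real number and the highest other were 8189 and 0 for IL_6h against Ctrl_0h, 9659 and 0 for IL_24h, 5978 and 0 for TNF_6h, 5458 and 9 for TNF_24h, 8866 and 0 for IL_TNF_6h and 8722 and 0 for IL_TNF_24h. They were 1861 and 0 for TNF added to IL at 6 h, 2428 and 0 at 24 h, 8993 and 0 for IL added to TNF at 6 h and 8281 and 0 at 24 h. Between times they were 4103 and 0 under IL, 4273 and 0 under TNF and 3915 and 0 under all 3 cytokines. For the interaction, 4 of 100 splits reached the real number at 6 h (2530, highest other 4902) and 4 of 100 at 24 h (3563, highest other 5811). These splits exchanged the labels of TNF among the libraries with IL and among those without it. They also break up the effects of TNF themselves, so their count cannot test the interaction and no conclusion is drawn from it. At each time 3 splits called more genes than the real one. The highest exchanged all 6 labels of the TNF and Ctrl_0h libraries and 0 of those with IL, so that the difference of the effects becomes their sum. The 2 others also exchanged 2 and 4 of the 6 labels with IL at 6 h and 2 and 2 at 24 h, and the reason for their numbers was not tested. For the change with time 2 of 100 splits reached the real number (591, highest other 659). Its splits exchanged the labels of TNF within each time and cannot test the change for the same reason.

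The division into 3 sets was seen at Xist, Ddx3y, Ifi202b and the last 86 gene identifiers. A response to IL-4 and IL-13 was excluded for Xist and Ddx3y, because Xist changed by -11.71 in IL_24h and by 1.54 in IL_6h against Ctrl_0h, in cells that received the same cytokines, and the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to at least 120 CPM in each IL library of 24 h and to at most 0.135 CPM in any other. For the last identifiers such a response was not excluded. Of those with at least 100 counts in the IL libraries 19 of 19 had none in the 9 others. This follows from how they were chosen, so the count cannot test a response. In the rest of the table identifiers of this kind were rare, 23 of 14463 or 0.159%. For Ifi202b a response to IL at 6 h and a difference between sets cannot be told apart, since the IL libraries of 6 h are themselves a set, with at least 30.3 CPM against 0 elsewhere. Xist and the Y-linked genes argue against cells of the same animals in the IL libraries of 24 h and in the others. Xist had at most 0.145 CPM in the IL libraries of 24 h and at least 162 CPM elsewhere. The lowest Ddx3y level in the IL libraries of 24 h was 41.8 CPM and the highest elsewhere 0. This is the pattern of male cells in the IL libraries of 24 h and female cells elsewhere. Comparisons between them thus also carry a difference of animals and sex. Whether the IL libraries of 6 h came from other animals than the Ctrl_0h and TNF libraries stays open. A reference without the last identifiers for the Ctrl_0h and TNF libraries remains open for those identifiers, with at least 10263 counts in each IL library and 0 in the others.

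Replicate 2 of Ctrl_0h had counts in 1384 genes that were silent elsewhere. Greater depth was excluded, since this library had 28.1 M counts, the fewest of all. The silent genes richest in CpG had 6.42 times as many reads per kb as the poorest (bootstrap interval 5.29 to 7.86). This argues against genomic DNA spread evenly over the genome. The ratio was not corrected for how uniquely reads can be placed or how well they amplify. Such DNA is thus not excluded. Fragments rich in CpG from another kind of library remain a candidate explanation, with the same ratio of 6.42. No biological explanation was tested.

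Replicate 1 of IL_TNF_24h stood apart from replicates 2 and 3. An exchange with a library of another set was excluded, as its Ddx3y level was 42.6 CPM, and an exchange with an IL_24h library as well, since 0 of these correlated best with another group. A shorter exposure may account for part of it, as its genes lay a median 28.9% of the way to the 6 h level (quartiles 4.41 to 57.6), but its Nos2 level of 269 CPM lay above both 23.6 CPM at 6 h and 46.2 and 44.6 CPM in the other replicates. A stronger response to TNF stays open, as the median ratio of its shift from IL_24h to that of the other replicates was 1.01 (0.971 to 1.05), which includes 1, beside 0.797 and 0.847 in replicates 2 and 3.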

How the results depend on the processing

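The alternative with 3 libraries left out together, replicate 2 of Ctrl_0h, replicate 3 of TNF_6h and replicate 1 of IL_TNF_24h, was chosen after the data were seen, and all others beforehand. Of 1085 gene values followed, 1007 were called. Of these, 958 kept their direction and call under every alternative set before the data were examined that tested them, other than leaving out single libraries. With single libraries and the 3 libraries left out as well, 909 did. A value that an alternative did not test counted as kept. The DESeq2 Wald test held 1028 of the 1085 values, the fit of the compared groups alone 1060 and the strict filter 1075. The other 78 of the 1085 values were not called in the main fit, and 32 of them had another sign under some alternative in which they were not called either. Total numbers of genes called in the 13 comparisons of a pair of groups and in both interactions stayed within 1.5 times their value under the normalization, the filters, the DESeq2 Wald test, the fit of the compared groups alone, the replicate number as a block and each library left out. Of the genes called, those lowered by TNF in the presence of IL at 24 h moved further, from 791 to 511 and 508 without replicates 1 and 2 of IL_24h, as did those raised in the interaction at 24 h, from 1812 to 1043 without replicate 2 of IL_24h. A change of 2-fold was recovered in simulated data for 54 of 100 genes and of 4-fold for 77 of 100, so smaller changes can be missed at this depth and group size. Only these genes were changed among 15323 tested, while 2193 were called between IL_TNF_6h and IL_6h in the real data. The adjustment of p values depends on how many genes change, so these rates need not hold for the real comparisons.

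The number of genes with a change of the TNF effect between times, 573, was 992 with the 3 libraries left out, 943 with the DESeq2 Wald test and between 343 (without replicate 1 of IL_24h) and 698 (without replicate 1 of IL_TNF_24h) with single libraries left out. The share of IL-raised genes lowered by TNF at 6 h, 8.30%, was 9.51% with the DESeq2 Wald test, 10.1% with the strict filter, 10.2% with the 3 libraries left out, 5.61% for genes raised at least 4-fold and between 5.37% (without replicate 2 of IL_TNF_6h) and 9.48% (without replicate 2 of Ctrl_0h) with single libraries left out. At 24 h the share of 5.79% was 7.56% with the Wald test, 6.75% without a filter, 7.33% with the strict filter, 4.40% for genes raised at least 4-fold and between 3.63% (without replicate 2 of IL_24h) and 7.24% (without replicate 2 of Ctrl_0h) with single libraries left out. With the replicate number as a block the shares were 8.36% and 5.92%. Of 224 tests of a gene list 131 were called, and 36 with an estimated correlation between genes, 132 with the block, 160 with the test fry and 126 with the 3 libraries left out. The cause was not tested for these differences, apart from the estimated correlation, which lowers the calls by its construction. The replicate number showed no pairing of libraries, since in 0 of 13 comparisons all 3 correlations of same-numbered libraries exceeded 0.1 (values between -0.310 and 0.363). A pairing across different numbers was not tested and stays open. Replicate 2 of IL_6h and replicate 3 of IL_TNF_6h shared a high level of Col1a1 (5.234 and 4.076 CPM) that the other libraries of these groups lacked.

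Some gene values changed sign, nearly all of them without a call. With the strict filter Tnf in IL_6h against Ctrl_0h was -0.00450 and Il4ra in TNF_24h against Ctrl_0h -0.0388. With the replicate block Retnla in TNF_6h against Ctrl_0h was -0.0258. With the 3 libraries left out, Chil3 was 3.42 and Il4ra -0.0835 in TNF_6h against Ctrl_0h, and Arg1 was -0.39, Chil3 0 and Il4ra -0.11 in TNF_24h. In IL_TNF_24h against Ctrl_0h Socs3 became called at 0.69 and Il4ra was -0.0957. In the interaction at 6 h Mmp25 was -0.0605 and Chil3 -4.75. In that at 24 h Aldh1a2 was -0.0929, Arg1 0.0713, Chil3 -0.55 and Nos2 became called at -7.11. For the change with time Ccl17 was 0.0441 and Socs1 -0.00370. Leaving out replicate 2 of Ctrl_0h alone gave the same signs for Chil3 and Il4ra in TNF_6h, Arg1, Chil3 and Il4ra in TNF_24h, Socs3 and Il4ra in IL_TNF_24h, Chil3 in both interactions and Aldh1a2 and Nos2 in that at 24 h, the last without a call (-5.68), and took Mmp25 to 0.0533. Leaving out replicate 1 of IL_TNF_24h alone did so for Nos2 (-0.66) and Ccl17 (0.0501). For the others the cause was not tested.

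With single libraries left out the sign changed, or the value reached 0, within these ranges. Values of Arg1, Retnla, Chil3 and Nos2 rest on few counts or 0 counts in a group and are no measure of size. Against Ctrl_0h, IL_6h gave Tnf between -0.0701 and 0.16 and Socs3 between -0.16 and 0.95, and IL_24h gave Nos2 between -0.0518 and 7.09. TNF_6h gave Arg1 between -0.24 and 4.11, Chil3 between -4.69 and 2.92, Socs3 between -0.16 and 0.95 and Il4ra between -0.0888 and 0.16. TNF_24h gave Arg1 between -0.41 and 3.82, Retnla between 0 and 3.44, Chil3 between -5.35 and 0 and Il4ra between -0.13 and 0.12. IL_TNF_24h gave Il1b between -0.44 and 1.68, Socs3 between -0.38 and 0.73 and Il4ra between -0.0698 and 0.18. Between IL_TNF_6h and IL_6h the values were Ccl24 between -0.24 and 0.0806 and Il4ra between -0.0508 and 0.24. Between IL_TNF_24h and IL_24h they were Il1b between -0.90 and 0.63. Between IL_TNF_24h and TNF_24h they were Nos2 between -0.00250 and 1.81, the low end without replicate 1 of IL_TNF_24h. From 6 h to 24 h under IL they were Socs1 between -0.37 and 0.0386 and Il4ra between -0.0998 and 0.12. Under TNF they were Arg1 between -0.81 and 0.33, Retnla between 0 and 3.44, Chil3 between -3.41 and 0, Nos2 between -0.27 and 0.0340 and Il4ra between -0.0798 and 0.00270. The interaction at 6 h gave Chil3 between -4.26 and 3.35, Socs1 between -0.92 and 0.19 and Il4ra between -0.18 and 0.17. That at 24 h gave Aldh1a2 between -0.0769 and 7.12, Chil3 between -0.77 and 4.58 and Nos2 between -5.68 and 1.47. The change with time gave Ccl17 between -0.66 and 0.0501 and Socs1 between -0.19 and 0.23.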

Other observations

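The genes of this part were chosen after their values were seen, and no further test was run on them. The genes Abca1, C3, Apol7c and Aldh1a2 were higher with all 3 cytokines than with either treatment alone at 24 h. Whether they stand for a group of genes was not tested. The cholesterol efflux list, which holds only Abca1 of them, was not called in IL_TNF_24h against IL_24h (camera adjusted p 0.624). The cholesterol transporter gene Abca1 stood at 37.5 ± 6.42 CPM in Ctrl_0h, 143 ± 3.99 CPM in IL_24h, 151 ± 42.2 CPM in TNF_24h and 322 ± 46.6 CPM in IL_TNF_24h. Apoe followed another course, from 11256 ± 707 CPM in Ctrl_0h to 747 ± 348 CPM in IL_TNF_24h. Complement C3 stood at 1248 ± 203 CPM in TNF_24h, 324 ± 7.70 CPM in IL_24h and 6152 ± 475 CPM in IL_TNF_24h. Apol7c had 11.3 ± 1.58 CPM with IL, 11.7 ± 5.001 CPM with TNF and 359 ± 172 CPM with all 3 cytokines at 24 h. Aldh1a2 had 10.8 ± 1.28 CPM in IL_24h, 0.0313 ± 0.0304 CPM in TNF_24h and 112 ± 4.02 CPM in IL_TNF_24h.

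Acod1 took the opposite order between the times. With all 3 cytokines it had 1347 ± 70.4 CPM at 6 h against 539 ± 18.7 CPM with TNF alone, and at 24 h 275 ± 112 CPM against 1514 ± 165 CPM with TNF alone. Tnf had the same order, with 212 ± 12.9 against 120.2 ± 9.36 CPM at 6 h and 9.05 ± 2.01 against 419.7 ± 48.99 CPM at 24 h. The ribosomal RNA gene mt-Rnr1 of the mitochondria had 31.7 ± 51.5 CPM in TNF_24h, where 1 of the 3 libraries carried most of it, and 537 ± 22.4 CPM in TNF_6h.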
